A study of Homo sapiens with 265 samples.

How the data were processed

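Peak lists of 3 assays were analysed: ATAC-seq, which reads open chromatin, ChIP-seq of acetylated histone H3 (H3K27ac), which marks active promoters and enhancers, and ChIP-seq of the transcription factor HIF2α. The tissues were normal kidney, primary kidney tumours and metastases of patients with clear cell renal cell carcinoma, and the cell lines were 769P, 786-O, A498 and UMRC6. Of the 164 peak lists, 163 were used (55 ATAC-seq, 57 H3K27ac and 51 HIF2α), and 1 HIF2α list of adjacent normal tissue, a group with no replicate, was not used. The labels list 265 samples, of which 101 had no peak list. These RNA-seq and input samples were not analysed here, and 3 RNA-seq samples had labels that contradict each other and were left in no group.

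Each deposited list holds 1 row per peak with its chromosome, start, end, name and a −log10 p-value or q-value of the peak caller, as the values show, with a smallest value of 2. Which of these the authors wrote is not given in the sources used here, and the lists carry no summit, fold enrichment or read count. BWA, MACS2 2.1.2 and the human genome build hg19 are named in the submitters' processing notes, and the largest end on chromosome 1 (249240605) lies within that chromosome's hg19 length of 249250621. The authors made a list for each library separately. Whether input libraries served as controls, and the reads sequenced per library, are not given in the sources used here. The depth behind a list is therefore unknown, and the number and total length of a library's peaks stand in for it. A peak that was not called can be absent or below the depth of that library.

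Groups were taken from the labels. Donor labels tie each of the 11 normal kidney libraries to a primary tumour library of the same donor in each assay. Where a donor gave several metastases, the first listed was used, which left 26 donors for ATAC-seq, 27 for H3K27ac and 22 for HIF2α. Of these, 9, 8 and 8 donors also gave a primary tumour. Only the 22 autosomes were used. A library with fewer than 5000 autosomal peaks was left out of every test except that of peak number, which removed 1 HIF2α metastasis library and left 21.

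Before the data were examined, the following tests were fixed. Consensus regions were stretches of at least 100 bp covered by peaks of 3 or more libraries of an assay. The presence of a peak (1 bp or more) in each region was compared between groups with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over regions at 0.05. Peak numbers, the share of a library's peaks on each of 40 chromosome arms, and the share of HIF2α peaks that overlap (1 bp or more) an H3K27ac peak of the same tissue of the same donor were compared with two-sided permutation tests (100000 resamples, exact where a group had fewer than 10 values). For a donor with several metastases, the HIF2α and H3K27ac lists can come from different metastases. The smallest p that 100000 resamples can give is 2e-05. Overlap between sets of regions was tested with Fisher's exact test over regions, which are not independent replicates. Named regions were the 10 per direction with the smallest p, ties going to the larger difference in share, then to the region covered in more libraries.

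A second test had been planned on gene loci, with gene lists, cell type markers and motifs. No hg19 gene annotation or sequence was used here, so these were not run and no region was assigned to a gene. In their place, chosen after seeing the files, the same model was fitted to fixed 50-kb windows: limma (trend) on log2(kb covered by peaks + 0.5), with all 4 groups of an assay in 1 fit, log2 of the library's total covered length as covariate, and windows covered in 3 or more libraries. Fold differences are on that log2 scale, which understates the change of windows with little coverage. The fit shares 1 spread per window over all groups, so that groups listed at 0 lower that spread and the p-value. This favours the call of losses over gains in tumours where metastases and lines are also at 0. Named windows were the 8 per direction with the smallest p among those with an adjusted p below 0.05 and an absolute log2 difference of at least 0.5, skipping neighbours of a window already taken. Positions are hg19, counted from 1, with chromosome bands from the hg19 band table of circlize. Genes are mentioned only as background on what a band is known to hold.

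Where donors pair the tissues, the pairing was checked on the deviations of window values from their group means. The mean correlation of libraries of the same donor was 0.017 in ATAC-seq, 0.096 in H3K27ac and 0.152 in HIF2α, and the correlation that limma estimated for a donor was 0.138, 0.173 and 0.0897. The pairing comes from the donor labels, and in ATAC-seq the label of 1 of the 11 pairs is not written alike in both libraries and was read as the same donor, so that the paired ATAC-seq results rest on that reading. Blocked alternatives used exact McNemar tests for regions, exact sign-flip permutation for shares and peak numbers, and a donor block in limma for windows.

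A window that changed between normal kidney and primary tumours counted as closer to tumours in another group when its mean covered length lay beyond the midpoint of both, or, chosen after seeing the data, when the same held for the group differences of the limma fit. Other alternatives were peaks with a value of 5 or more, equal list lengths (the 20000 strongest peaks, 10000 for HIF2α, with libraries of fewer peaks left out, so that 9 normal kidneys and 23 metastases remained in ATAC-seq), 50% of a region covered, 1-kb tiles covered over at least 500 bp, regions of 1 or more libraries, all metastasis libraries, each cell line left out, pseudocounts of 0.1 and 2 kb, no covariate, no filter on low windows, 100-kb windows, libraries below 1 / 3 of the assay's median covered length left out, and adjustment only over regions whose totals can reach a p of 0.001. Both tests were tested on simulated data. With H3K27ac libraries of 11 tumours and 11 normal kidneys, the region test recovered 36% of 100 regions present in 95% against 5% of libraries and 0% of those present in 80% against 20%, among 159173 regions. With 27 metastases and 11 primary tumours it recovered 95% and 17%, and with 4 cell lines 0% of either. The adjustment is stricter where few regions change, as in this simulation, so that these shares can understate the recovery where many do. The window fit of tumours against normal kidney recovered 49% of 100 windows with a log2 change of 1 and 87% of those with a change of 2, with 8 false calls, among 34773 windows. Its values were drawn independently with the spread of the tumours, without donors or other structure of the samples. The 8 false calls are therefore no measure of the error in the real libraries, where the highest regrouped split called 725 H3K27ac windows and the next highest 24. Versions were Python 3.11.15, R 4.3.3, limma 3.58.1, circlize 0.4.16, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.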

Results

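Active and open chromatin and HIF2α binding were mapped in normal kidney, primary clear cell renal cell carcinoma, its metastases and established cell lines of the same cancer. HIF2α, the product of EPAS1, is a hypoxia-inducible transcription factor that accumulates when the tumour suppressor VHL on 3p is lost. Lists of 11 normal kidneys and 11 primary tumours of the same donors were available for each assay, with metastases of 26 donors for ATAC-seq, 27 for H3K27ac and 22 for HIF2α, and lists of 4 cell lines (769P, 786-O, A498 and UMRC6). Normal kidney held 33516 ± 12816 ATAC-seq peaks, 71977 ± 9035 H3K27ac peaks and 55889 ± 22734 HIF2α peaks per library (mean ± SD, n = 11). These covered 16.4 ± 7.15, 92.9 ± 24.29 and 35.7 ± 23.8 Mb of the autosomes. The depth of sequencing behind each list is unknown.

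Metastases carried fewer HIF2α peaks than primary tumours, and cell lines fewer H3K27ac peaks. HIF2α peaks numbered 36889 ± 20343 in metastases (SD, n = 22) and 56719 ± 24294 in primary tumours (n = 11, two-sided permutation p = 0.0216). The metastases include 1 list of 75 peaks, without which the difference was -18077 (permutation p = 0.0322). In this comparison 8 donors gave both tissues, which the test ignores, and no paired test was run. The p-values of peak numbers were not adjusted over comparisons. Primary tumours and normal kidney did not differ in mean number of HIF2α peaks beyond wide spreads (permutation p = 0.930; paired by donor, exact sign-flip permutation p = 0.928), although the tumour list was longer in 9 of 11 pairs. The 4 cell lines held 48562 ± 4704 H3K27ac peaks against 76566 ± 10262 in primary tumours (exact permutation p = 0.00147), a difference of -28004 that shrank to -10573 with peaks of value 5 or more (exact permutation p = 0.0278). ATAC-seq peaks averaged 42881 ± 10324 in primary tumours, which did not differ from normal kidney in the unpaired test (permutation p = 0.0734) and did when paired by donor (exact sign-flip permutation p = 0.0400, higher in 7 of 11 pairs). H3K27ac peak numbers behaved alike, with p = 0.276 in the unpaired permutation test and 0.0449 in the exact paired one (higher in 8 of 11 pairs). Metastases held 38775 ± 11923 ATAC-seq peaks (n = 26; permutation p = 0.328 against primary tumours) and 67183 ± 15249 H3K27ac peaks (n = 27; permutation p = 0.0619). The cell lines held 47404 ± 7853 ATAC-seq and 60767 ± 8485 HIF2α peaks, with exact permutation p = 0.466 and 0.750 against primary tumours.

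**Figure D1:**
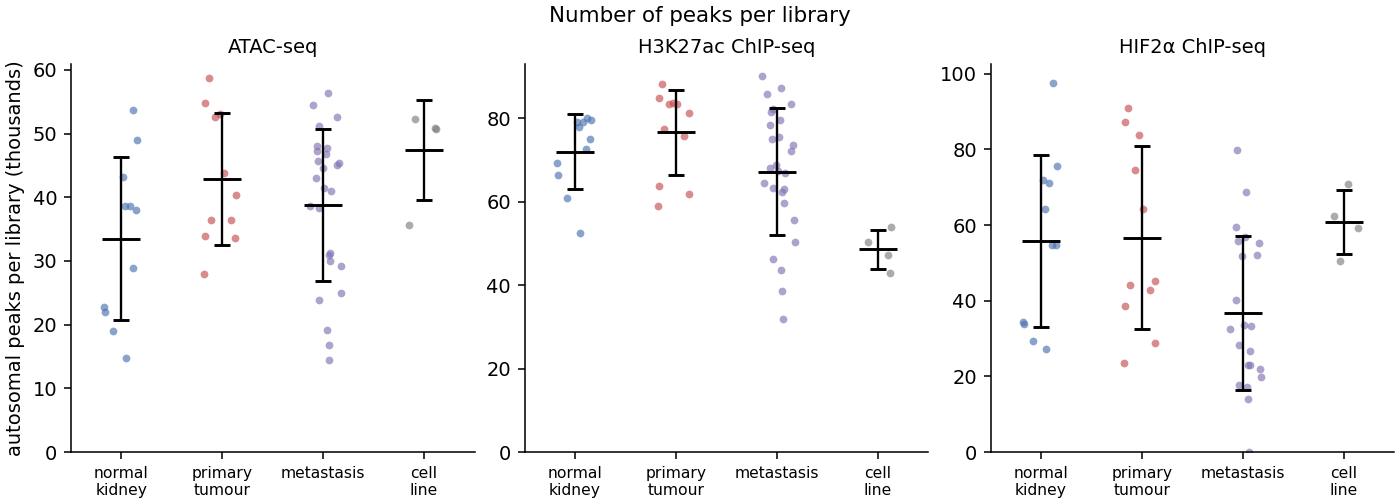
Autosomal peaks per library by assay and tissue, each point a library, with the mean and SD as bars; metastases are the first listed of each donor. HIF2α lists are shorter in metastases (mean 36889) than in primary tumours (mean 56719), and the 4 H3K27ac lists of cell lines lie between 42839 and 53852 peaks.

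Primary tumours gained and lost acetylated chromatin at many loci relative to normal kidney, and more losses than gains were called. In 50-kb windows, H3K27ac coverage rose at 2613 and fell at 3346 of 34773 windows (limma, adjusted p below 0.05). The shared spread of the fit favours the call of losses, so these counts do not measure the balance. The median log2 difference over all windows was 0.0573. The strongest gain lay at 12q24.32 (chr12:129250001-129300000), where acetylated length rose from 0.211 ± 0.408 kb in normal kidney to 11.4 ± 6.34 kb in tumours (log2 difference 3.93, SE 0.332, adjusted p = 1.83e-13), higher in 11 of 11 tumours than the normal mean. At 12q13.3 (chr12:57600001-57650000) it rose from 5.42 ± 2.56 to 19.1 ± 3.10 kb (log2 difference 1.80, SE 0.155, adjusted p = 3.77e-13). The band 12q13.3 is known to hold NDUFA4L2, a mitochondrial protein induced by hypoxia. Further gains lay at 3q21.3 (chr3:126600001-126650000, 0.379 to 5.64 kb), 1p32.1 (chr1:59500001-59550000, 2.19 to 19.4 kb), 1p34.1 (chr1:44850001-44900000, 0.0306 to 5.64 kb), 7p21.1 (chr7:17250001-17300000, 0.150 to 1.70 kb), 10p15.1 (chr10:6200001-6250000, 10.5 to 27.2 kb) and 15q26.3 (chr15:102150001-102200000, 3.83 to 16.9 kb). Each of these 6 had an adjusted p of 1.51e-09 or less, but with equal list lengths those at 1p34.1 and 7p21.1 were no longer called (log2 difference 1.58 and 1.18 instead of 3.09 and 1.85, adjusted p = 0.0603 and 0.0536).

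Some windows with broad acetylation in normal kidney had none left in tumours. At 14q24.3 (chr14:76750001-76800000) normal kidney carried 11.3 ± 7.65 kb and all 11 tumours, 27 metastases and 4 cell lines were listed at 0 (log2 difference -4.28, SE 0.203, adjusted p = 6.83e-23). At 18q21.1 (chr18:48150001-48200000) normal kidney carried 4.79 ± 1.78 kb and the same tumours, metastases and lines were likewise at 0 (log2 difference -3.31, SE 0.130, adjusted p = 1.53e-26). At 2q37.1 (chr2:233500001-233550000) coverage fell from 22.5 ± 8.13 to 0.439 ± 0.671 kb. Coverage at 8p11.21 (chr8:41150001-41200000) fell from 5.15 to 0.0236 kb, at 13q12.11 (chr13:22250001-22300000) from 7.86 to 0.0224 kb, at 1p36.13 (chr1:18000001-18050000) from 6.15 to 0 kb, at 4p16.3 (chr4:2050001-2100000) from 9.95 to 0.0474 kb and at 12q21.31 (chr12:86650001-86700000) from 0.735 to 0 kb. Each of these 8 windows was lower in 11 of 11 pairs, with an adjusted p of 3.71e-19 or less. Libraries listed at 0 add no spread to the fit, which makes these p-values smaller. With equal list lengths all 8 were still called, with smaller log2 differences: -1.39 instead of -3.73 at 13q12.11, -2.32 instead of -4.28 at 14q24.3, -1.91 instead of -3.31 at 18q21.1, -2.14 instead of -3.54 at 1p36.13 and -0.790 instead of -1.27 at 12q21.31.

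Single acetylated regions changed in the same way. A peak was present in 11 of 11 tumours and 0 of 11 normal kidneys at 8q24.21 (chr8:128838168-128846743), a band known to hold the proto-oncogene MYC, and also at 19p13.3 (chr19:6596385-6604187), 2p16.1 (chr2:58103560-58111075), 22q11.21 (chr22:19014163-19023764), 5q33.3 (chr5:159657158-159663764) and 16q24.2 (chr16:88364930-88368183). The 10 gained regions named by the rule, these 6 among them, were also present in 19 to 25 of 27 metastases. The reverse, 0 of 11 tumours and 11 of 11 normal kidneys, held at 168 regions, among them 3p22.2 (chr3:36530825-36536607), 1p36.11 (chr1:27233443-27238831), 6p21.1 (chr6:41654564-41658438) and 9q34.3 (chr9:139247881-139250767). The 10 lost regions named by the rule, these 4 among them, were present in 4 to 9 of 27 metastases and in 0 to 4 of 4 cell lines, those at 3p22.2 and 1p36.11 in 4 of 4 lines. Ties in p were broken by the number of libraries covered, metastases and cell lines included. The rule thus favoured regions present in those groups, so that these counts do not describe the other gained and lost regions. In all, 351 regions were more and 1159 less often acetylated in tumours among 159173 (Fisher's exact test, smallest adjusted p = 0.00238). Paired by donor, the exact McNemar test, whose smallest possible p with 11 pairs is 0.000977, called 0 regions.

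**Figure D2:**
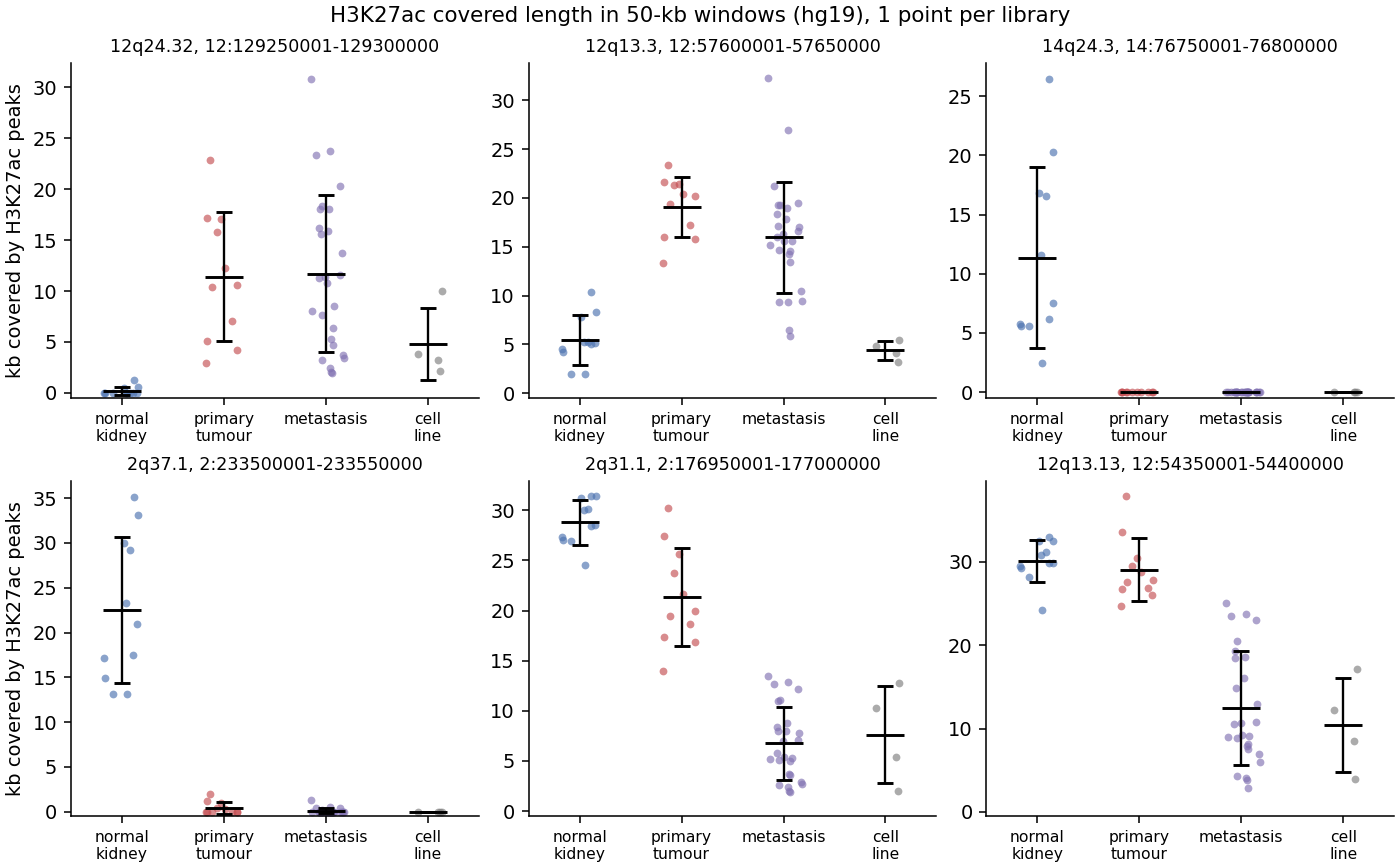
Length covered by H3K27ac peaks (kb) in 6 windows of 50 kb, each point a library, with the mean and SD as bars. The windows at 12q24.32 and 12q13.3 rise from 0.211 and 5.42 kb in normal kidney to 11.4 and 19.1 kb in primary tumours, those at 14q24.3 and 2q37.1 fall from 11.3 and 22.5 kb to 0 and 0.439 kb, and those at 2q31.1 and 12q13.13 average 21.4 and 29.1 kb in primary tumours and 6.75 and 12.4 kb in metastases.

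HIF2α coverage was redistributed between tumours and normal kidney, rising at 1745 and falling at 3577 of 39938 windows (limma). Without the covariate for total covered length these were 387 and 1665, a share of rising windows of 18.9% instead of 32.8%. The largest gain by p was at 6p21.1 (chr6:44000001-44050000), from 4.62 ± 6.18 kb in normal kidney to 16.4 ± 6.41 kb in tumours (log2 difference 2.02, SE 0.230, adjusted p = 2.60e-08; higher in 10 of 11 pairs), in a band known to hold the angiogenic factor VEGFA. Coverage also rose at 12q13.3, in the window that gained acetylation, from 2.35 to 7.80 kb (adjusted p = 3.22e-06). Further gains were at 12q24.33 (chr12:129300001-129350000, 1.02 to 4.41 kb), next to the strongest acetylation gain, 21q21.3 (chr21:30600001-30650000, 0.534 to 2.76 kb), 17q23.2 (chr17:60950001-61000000, 0.479 to 2.61 kb), 2p12 (chr2:75050001-75100000, 1.52 to 5.42 kb), 10p15.2 (chr10:3050001-3100000, 0.886 to 3.79 kb) and 12q22 (chr12:92950001-93000000, 1.97 to 6.06 kb). Each was higher in 10 of 11 pairs with an adjusted p of 3.60e-06 or less.

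HIF2α peaks of normal kidney were lost at 14q24.3, the window that lost its acetylation, from 1.87 ± 1.61 to 0 kb (adjusted p = 5.91e-09). They were also lost at 15q26.3 (chr15:100600001-100650000, 0.507 to 0 kb, adjusted p = 2.09e-11), 20q13.2 (chr20:50850001-50900000, 0.840 to 0.0256 kb), 13q11 (chr13:19350001-19400000, 0.878 to 0 kb), 2p13.3 (chr2:71150001-71200000, 0.890 to 0.0218 kb) and 14q32.13 (chr14:95800001-95850000, 2.08 to 0.222 kb). With equal list lengths the loss at 13q11 was no longer called (log2 difference -0.354 instead of -1.38, adjusted p = 0.0845), and the windows at 14q24.3 and 20q13.2 were not measured in HIF2α. Among 153776 regions, 23 were bound more and 101 less often in tumours (Fisher's exact test). A peak at 2q14.3 (chr2:122993492-122996358) was present in 11 of 11 tumours and 0 of 11 normal kidneys (adjusted p = 0.0335), and a peak at 8q24.21 (chr8:128871409-128873504) in 10 of 11 and 0 of 11 (adjusted p = 0.0422). The region count fell to 0 when 50% of a region had to be covered, with 1-kb tiles, and when regions of 1 or more libraries were used. It was also 0 when paired by donor, where the smallest possible McNemar p of 0.000977 hardly lets a region pass adjustment.

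Fewer windows passed for open chromatin. ATAC-seq coverage rose at 68 and fell at 187 of 39648 windows (limma); without the covariate it rose at 1849 and fell at 136, so that the direction of the majority depends on that choice. When paired by donor, 195 windows rose and 443 fell. Gains included 7q31.2 (chr7:116150001-116200000, 0.701 ± 0.810 to 2.87 ± 0.993 kb, adjusted p = 0.00130), a band known to hold CAV1, 2q22.1 (chr2:136850001-136900000, 0.438 to 3.24 kb, adjusted p = 0.00172), a band known to hold the chemokine receptor gene CXCR4, 1q42.13 (chr1:228750001-228800000, 1.67 to 4.93 kb), 10p13 (chr10:12350001-12400000, 0.593 to 2.14 kb) and 8q13.3 (chr8:72750001-72800000, 0.308 to 1.60 kb). At the 7q31.2 and 2q22.1 windows H3K27ac rose too, from 2.57 to 8.78 kb and from 6.70 to 16.8 kb (adjusted p = 2.98e-07 and 0.000211). Losses included 22q13.1 (chr22:37750001-37800000, 1.03 to 0.0957 kb, adjusted p = 0.00212), where H3K27ac fell from 4.03 to 0.118 kb, 3p12.3 (chr3:74850001-74900000, 0.519 to 0.0157 kb) and 9q33.2 (chr9:122750001-122800000, 0.428 to 0.0153 kb). No single ATAC-seq region among 107056 passed Fisher's exact test after adjustment, with 5274 higher and 704 lower at an unadjusted p under 0.05. With equal list lengths, a setting that also leaves out libraries with fewer peaks (11 tumours and 9 normal kidneys remain) and has 44722 regions, these were 1349 and 1946, so that the direction of the majority depends on that setting.

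The assays moved together. Of the windows measured in both, 860 rose in H3K27ac and in HIF2α, against 129 for independent lists, and 1567 fell in both against 298. Only 7 and 2 windows went in opposite directions. Of the 68 windows that gained ATAC-seq coverage, 54 gained H3K27ac, against 5.31 for independent lists, and no window went in opposite directions in these assays. Across windows, which are not independent replicates, the log2 differences of H3K27ac and HIF2α had a Spearman rho of 0.647. Of the 351 acetylated regions gained in tumours, 69.8% overlapped a HIF2α region present in 6 or more of the 11 tumours and of the 1159 lost regions 1.55% did, while 45.4% of the lost regions overlapped a HIF2α region of 6 or more normal kidneys. These regions were chosen by their acetylation in the same tissues and most HIF2α peaks lie in acetylated chromatin, so that the choice of regions largely sets these shares. Within a tissue, 69.4 ± 10.3% of HIF2α peaks overlapped an H3K27ac peak of the same donor in tumours and 64.7 ± 11.6% in normal kidney (n = 11 each, permutation p = 0.329), where random placement would give 5.06% and 4.71%. In metastases it was 70.6 ± 13.03% (n = 21, permutation p = 0.784 against tumours). Among donors with 1 metastasis library it was 71.4 ± 13.5% (n = 19, permutation p = 0.667).

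Peaks were unevenly distributed over chromosome arms. The share of peaks on 3p was lower in tumours than in normal kidney in all 3 assays: 2.18 ± 0.195% against 2.67 ± 0.280% in ATAC-seq (adjusted permutation p = 0.0104, lower in 10 of 11 pairs), 2.54 ± 0.192% against 2.93 ± 0.0626% in H3K27ac (adjusted p = 0.0004, lower in 10 of 11 pairs) and 2.46 ± 0.254% against 2.81 ± 0.136% in HIF2α (adjusted p = 0.0088, lower in 9 of 11 pairs). Loss of 3p and gain of 5q are the recurrent chromosome changes of this cancer. These arms did not stand alone. The largest H3K27ac difference lay on 1p (5.65 ± 0.342% against 6.21 ± 0.233%, adjusted permutation p = 0.000457, lower in 10 of 11 pairs). In HIF2α the smallest adjusted permutation p lay on 10p (0.0064, higher in 10 of 11 pairs). Copy number was not measured here. The share on 5q was higher in ATAC-seq (4.39 ± 0.293% against 3.94 ± 0.224%, adjusted p = 0.0188) and H3K27ac (4.48 ± 0.329% against 4.03 ± 0.144%, adjusted p = 0.00175, higher in 11 of 11 pairs), while the HIF2α difference did not pass. Shares of H3K27ac peaks were also higher on 3q, 7p, 8q, 10p, 11q and 12p in 11 of 11 pairs, and lower on 4p, 9q and 11p in 11 of 11 pairs. When paired by donor, the exact sign-flip test called 0 arms in ATAC-seq and HIF2α.

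**Figure D3:**
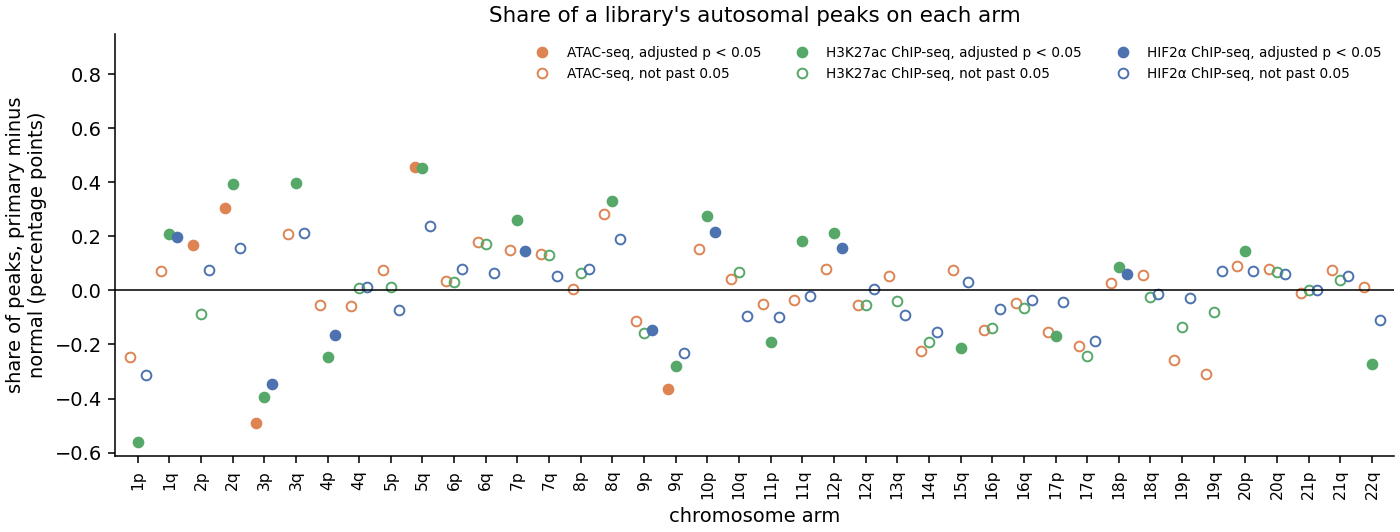
Difference in the mean share of a library's autosomal peaks on each chromosome arm, primary tumours minus normal kidney (percentage points, n = 11 each); filled points have an adjusted permutation p under 0.05. The 3p points lie at -0.489 (ATAC-seq), -0.393 (H3K27ac) and -0.347 (HIF2α), and the ATAC-seq and H3K27ac points of 5q at 0.457 and 0.451. The lowest point is that of H3K27ac on 1p, at -0.562.

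Metastases differed from primary tumours at few loci. H3K27ac rose at 4 and fell at 49 of 34773 windows (limma). At 2q31.1 (chr2:176950001-177000000), a band known to hold the HOXD cluster of developmental transcription factors, metastases carried 6.75 ± 3.62 kb (n = 27) against 21.4 ± 4.91 kb in primary tumours and 28.8 ± 2.23 kb in normal kidney (n = 11 each; log2 difference -1.52, SE 0.192, adjusted p = 3.26e-06), below the tumour mean in 27 of 27. At 12q13.13 (chr12:54350001-54400000), a band known to hold the HOXC cluster, they carried 12.4 ± 6.85 kb against 29.1 ± 3.78 kb in primary tumours and 30.1 ± 2.49 kb in normal kidney (log2 difference from primary tumours -1.27, SE 0.225, adjusted p = 0.00380), again below the tumour mean in 27 of 27. The 4 cell lines carried 7.63 ± 4.86 kb at 2q31.1 and 10.5 ± 5.61 kb at 12q13.13. Other losses were at 4q32.2 (chr4:164250001-164300000, 1.84 to 0.168 kb), 4q35.1 (chr4:186500001-186550000, 1.12 to 0.201 kb), 2q23.1 (chr2:149550001-149600000, 2.84 to 0.588 kb), 16q24.1 (chr16:87050001-87100000, 2.75 to 0.564 kb) and 1p13.2 (chr1:115850001-115900000, 6.57 to 1.49 kb). At 2q14.2 (chr2:121500001-121550000) both H3K27ac (7.49 to 1.42 kb, adjusted p = 0.00776) and HIF2α (2.14 to 0.471 kb, adjusted p = 0.0259) were shorter. The 4 windows that rose were at 1p34.2 (chr1:40250001-40300000, 1.84 to 5.08 kb), 7q21.2 (chr7:92350001-92400000, 3.04 to 5.13 kb), 16q22.1 (chr16:70500001-70550000, 0.719 to 1.99 kb) and 20p13 (chr20:1500001-1550000, 0.576 to 1.94 kb). Without the covariate 0 windows rose and 268 fell, and these 4 lost their call (adjusted p = 0.138 to 0.179). Most of these calls were lost with equal list lengths. With equal list lengths 14 windows were called, 8 of them among the 53. The losses at 2q31.1 and 12q13.13 and the gain at 1p34.2 were still past the threshold. The losses at 4q32.2, 2q23.1, 16q24.1, 1p13.2 and 2q14.2 were not (adjusted p = 0.259 to 0.948; log2 difference -1.06 to -0.0895 instead of -2.17 to -1.56), nor were the gains at 7q21.2 and 20p13 (log2 difference 0.992 and 0.489 instead of 1.57 and 1.23, adjusted p = 0.375 and 0.677). The gain at 16q22.1 kept its fold (log2 difference 1.25 instead of 1.22) and lost only its call (adjusted p = 0.307). The HIF2α loss at 2q14.2 was no longer called (log2 difference -0.423 instead of -1.24, adjusted p = 0.749), and 4q35.1 was not measured in those lists. With all metastasis libraries 135 were called.

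HIF2α coverage in metastases fell at 18 of 39938 windows and rose at 0 (limma). The smallest p lay at 2q35 (chr2:218250001-218300000, 2.81 ± 2.19 to 0.300 ± 0.385 kb, log2 difference -1.49, SE 0.213, adjusted p = 0.000225, below the tumour mean in 21 of 21), 10p15.3 (chr10:700001-750000, 3.66 to 0.768 kb), 14q12 (chr14:32450001-32500000, 2.46 to 0.269 kb) and 1p36.21 (chr1:15400001-15450000, 0.694 to 0.0506 kb). These calls depend on list length: without the covariate 1205 windows fell, and with equal list lengths 2 did, neither of them among the 18. Fisher's exact test called 9 HIF2α regions, all less frequent in metastases, among them 9p22.1 (chr9:19431229-19432281, present in 1 of 21 metastases and 11 of 11 primary tumours, adjusted p = 0.0131). With equal list lengths it called 0. The paired exact McNemar test also called 0, but its smallest possible p with 8 pairs, 0.00781, hardly lets a region pass adjustment. ATAC-seq differed at 0 of 39648 windows in limma (2730 at an unadjusted p under 0.05) and at 0 regions in Fisher's exact test (318 higher and 2419 lower unadjusted). H3K27ac regions likewise gave 0 calls in Fisher's exact test (294 higher and 6359 lower unadjusted).

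With list length adjusted for, most windows that changed between normal kidney and primary tumours were closer to the tumours in metastases. In the limma fit with total covered length as covariate, this held for 83.5% of the 2613 windows with gained H3K27ac and 98.4% of the 3346 with lost H3K27ac, for 81.8% of the 1745 with gained and 96.7% of the 3577 with lost HIF2α, and for 95.6% of the 68 with gained ATAC-seq coverage. The shares of gained H3K27ac and HIF2α windows depend on that adjustment, which was chosen after seeing the data. Without it, over the 2613 windows with gained H3K27ac, the median of the group means was 0.635 kb in normal kidney, 3.37 kb in primary tumours and 2.64 kb in metastases, and 66.2% of windows were closer to the tumour mean in metastases. For HIF2α that share was 17.4% of gained windows. Of lost windows, 99.3% in H3K27ac and 99.9% in HIF2α were closer to the tumours without the adjustment. A library with little coverage counts as closer to the tumours at a lost window. High shares of lost windows are thus partly built in, and no share over other windows was computed. HIF2α lists covered 21.6 ± 14.8 Mb in metastases (n = 22) against 38.2 ± 22.6 Mb in primary tumours. That mean of metastases includes the list of 0.02 Mb that the windows left out, so that the lists behind the share were somewhat longer. The windows were chosen on the same primary tumours and normal kidneys.

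Cell lines lay far from primary tumours in all assays. H3K27ac rose at 5372 and fell at 4059 windows, HIF2α rose at 6440 and fell at 4381, and ATAC-seq rose at 3532 and fell at 1646 (limma, 4 lines against 11 tumours). Without the covariate 3954 H3K27ac windows fell and 3719 rose, 922 HIF2α windows fell and 6487 rose, and 248 ATAC-seq windows fell and 2620 rose. Rising windows were then 48.5%, 87.6% and 91.3% of calls instead of 57.0%, 59.5% and 68.2%, so that the direction of the majority in H3K27ac depends on that choice. Some gains lay where normal kidneys, primary tumours and the first listed metastases had no peak, at 150 windows in H3K27ac, 116 in HIF2α and 59 in ATAC-seq. At 3q13.11 (chr3:105100001-105150000) the lines carried 8.55 ± 3.69 kb of H3K27ac and 2.35 ± 0.468 kb of HIF2α (n = 4), and primary tumours and normal kidney were listed at 0 in both assays (adjusted p = 2.83e-27 and 9.07e-21). Such p-values rest mostly on the lack of spread in tissues listed at 0 and say little about variation among the lines. At 7q31.2 (chr7:115200001-115250000) the lines carried 1.49 ± 0.194 kb of H3K27ac and 0.867 ± 0.293 kb of HIF2α, with those tissues at 0. At 9p24.1 (chr9:7850001-7900000) they carried 0.740 ± 0.214 kb of HIF2α and 0.485 ± 0.1002 kb of ATAC-seq coverage, again with those tissues at 0. Chromatin active in all tissues had little or no coverage in the lines at 18p11.21 (chr18:13200001-13250000), where H3K27ac was 6.51 ± 1.42 kb in primary tumours and 0 in the 4 lines, at 10p11.22 (chr10:31950001-32000000, 12.4 ± 2.58 kb and 0) and at 7q36.1 (chr7:150450001-150500000, 15.9 ± 4.70 and 0.406 ± 0.377 kb). Which cells of the tissues carried these peaks was not tested, so that a loss in tumour cells is not shown. HIF2α coverage at the 18p11.21 and 10p11.22 windows was 3.87 ± 2.24 and 3.87 ± 1.75 kb in tumours and 0 in the lines, but with equal list lengths the 18p11.21 difference was no longer called in HIF2α (log2 difference -0.719 instead of -3.30, adjusted p = 0.453). The 7q31.2 and 9p24.1 windows were not measured in HIF2α lists of equal length. Of the windows with H3K27ac gained in primary tumours, 51.3% were closer to the tumours than to normal kidney in the lines with the covariate and 40.4% without, and of those lost, 77.7% and 83.1%. At 12q13.3 the lines carried 4.39 ± 0.964 kb of H3K27ac, against 5.42 kb in normal kidney and 19.1 kb in tumours. Fisher's exact test, whose smallest possible p with 4 lines and 11 tumours is 0.000733, called 0 regions in each assay. Unadjusted, 4877 H3K27ac, 10326 HIF2α and 5275 ATAC-seq regions were higher and 7335, 5371 and 2092 lower. The majority in H3K27ac turned with equal list lengths (2374 higher and 1477 lower, of which 400 and 253 passed adjustment), with peaks of value 5 or more (5063 and 4597) and with 50% of a region covered (5927 and 2327). Without 769P, the ATAC-seq windows called were 3170 instead of 5178.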

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

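The tests of list length in this part, and the comparison of total covered lengths, were chosen after the results had been seen, and the other tests before them.

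Some values of single cell lines stood apart from the other 3 lines. Among 54 groups of 4 values examined, 5 were far from the rest by Dixon's criterion. Chance alone gives about 1 in 20, a rate that does not apply to 3 of the 5, at windows named for low coverage in the lines, where the other 3 lines were listed at 0 and any coverage meets the criterion. The ATAC-seq list of A498 held 35674 peaks, against 50777 to 52336 in the other lines. The line 769P had ATAC-seq coverage of 0.554 kb at 1p32.3 (chr1:51500001-51550000), against 0.285 to 0.321 kb. It also had ATAC-seq coverage of 0.731 kb at 18p11.21 (chr18:13200001-13250000), HIF2α coverage of 0.710 kb at 15q22.2 (chr15:60850001-60900000) and HIF2α coverage of 0.394 kb at 7p14.1 (chr7:37450001-37500000), the windows with the other 3 lines at 0.

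The shorter H3K27ac in metastases at the 2q31.1 and 12q13.13 windows, bands known to hold HOX clusters, was weighed against technical sources. Shorter lists do not account for it, since with equal list lengths the mean log2 difference of both windows was -1.73, against -1.39 without. Loss of the chromosome segment is argued against by the 111 windows within 2 Mb, whose median difference was -0.00515. Normal kidney cells within the primary tumours stay open: 104 other windows that were long in normal kidney and short in metastases and lines kept a median of 49.4% of their normal length in tumours, with quartiles of 29.6 and 64.9% around the 50% set beforehand, while the pair kept 74.2 and 96.6%. The cell lines, which hold no other cells of the tissues, carried 7.63 and 10.5 kb, near the metastases. Lines differed from primary tumours at many windows, so that these values do not settle the question. Other differences between kidney and the sites of metastasis were not tested, so that a change in tumour cells and a change in the cells sampled cannot be told apart.

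Mean numbers of HIF2α peaks were 55889 in normal kidney and 56719 in primary tumours, with the tumour list the longer in 9 of 11 pairs, and lost HIF2α windows outnumbered gained ones. Longer lists in normal kidney do not account for the excess of losses, since those lists were on average no longer than the tumour lists. With equal list lengths gained windows were 31.07% of those called. How far the shared spread of the fit, which favours the call of losses, adds to the excess was not tested. Fisher's exact test of regions, which shares no such spread, also called more losses (101) than gains (23). A candidate explanation is that many HIF2α peaks follow acetylated or open chromatin whatever the level of HIF2α. Of the 10101 windows with no H3K27ac difference, 4.92% were called for HIF2α, against 41.1% of windows with an H3K27ac call and 13.9% of all. The exact 95% binomial interval of 4.51 to 5.36% lies on both sides of the 5% set beforehand, and is too narrow because neighbouring windows are not independent. The interval keeps this open. A share below 5% would also arise if acetylation followed HIF2α, so that this test cannot tell which follows the other. Binding of HIF2α in normal kidney remains among the open explanations.

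Windows that lost H3K27ac in primary tumours outnumbered those that gained it. How far the shared spread of the fit, which favours the call of losses, adds to this excess was not tested. Fisher's exact test of regions, which shares no such spread, also called more losses (1159) than gains (351). Loss of 3p is not the whole cause, since 6.57% of the windows called lower lie on 3p, against 2.87% of the windows tested. Shorter lists of tumours are argued against by their total covered length, which was 4.14 Mb above that of normal kidney on average. Fewer cell types in tumours than in kidney, a biological difference between the tissues, was not tested.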

How the results depend on the processing

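Alternatives with windows, with adjustment over testable regions, without libraries of low covered length, and paired peak numbers were chosen after seeing the data; the others were planned. Except where the construction of an alternative shows it, the cause was not tested. Depth is unknown, so that lists of different length limit all presence calls. In the other comparisons of peak number, and for the overlap of HIF2α with H3K27ac, the alternatives run kept the side of the threshold. Differences without a call changed sign for the HIF2α peak number in tumours against normal kidney (-69.5 with peaks of value 5 or more, against 830) and for the HIF2α overlap with H3K27ac in metastases against tumours (-3.11 points with equal lists and -1.65 with the replicate block, against 1.22). Of the windows named, 416 of 428 alternative values in tumours against normal kidney, 160 of 199 in metastases against tumours and 553 of 558 in cell lines against tumours kept direction and call, and 0 reversed. With equal list lengths 16 of the 19 named windows measured in metastases lost their call. Named regions were less stable. Under the pairing 40 values in tumours against normal kidney and 9 in metastases lost their call. There the smallest possible McNemar p (0.000977 and 0.00781) hardly lets a region pass adjustment. With these included, 169 of 229 values in tumours against normal kidney and 46 of 64 in metastases lost their call, and 5 and 1 had a difference of 0. These were H3K27ac at chr7:23372688-23376572 (0 with equal lists), chr15:101974291-101983207 and chr4:53688910-53692853 (0 with 1-kb tiles) and chr15:67048799-67051111 (0 with regions of 1 or more libraries), and HIF2α at chr14:69199636-69200420 (0 with 1-kb tiles) and chr1:15414604-15415583 in metastases (0 with equal lists).

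With the replicate block (pairing by donor), the peak number difference between tumours and normal kidney, 9365 in ATAC-seq and 4590 in H3K27ac, passed the test. The block gave 0 regions in H3K27ac and HIF2α tumours against normal kidney and 0 in HIF2α metastases, where exact McNemar tests have a bounded smallest p. It gave 0 ATAC-seq and 0 HIF2α arms, and 638 ATAC-seq windows. It moved no other count by over 1.5 times, and among 6 arm shares followed through the alternatives, 3 lost their call under the pairing.

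The ATAC-seq peak difference was 10248 with peaks of value 5 or more, and passed. That setting gave 1006 H3K27ac regions in tumours, 1 in metastases, and 4 HIF2α windows in metastases. Equal list lengths gave 356 H3K27ac and 262 HIF2α regions in tumours, 653 H3K27ac regions in cell lines and 0 HIF2α regions in metastases. The same setting gave 418 ATAC-seq, 2238 H3K27ac and 1545 HIF2α windows in tumours. In metastases it gave 1, 14 and 2, and in cell lines 3142, 5231 and 4470. Covering 50% of a region gave 716 H3K27ac regions in tumours, and 0 HIF2α regions in tumours and in metastases. Tiles of 1 kb gave 2985, 9 and 3752 H3K27ac regions in tumours, metastases and cell lines, and 0 HIF2α regions in tumours and metastases. Regions of 1 or more libraries, which are more numerous, gave 531 H3K27ac and 0 HIF2α regions in tumours, and 2 HIF2α regions in metastases. Adjustment over testable regions alone, which are fewer, gave 623 ATAC-seq, 3294 H3K27ac and 1555 HIF2α regions in tumours. It gave 5 H3K27ac and 166 HIF2α regions in metastases, and 644, 2035 and 1648 regions in cell lines.

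Shares of covered length instead of peaks called 2 ATAC-seq and 3 HIF2α arms. Without the covariate, 1985 ATAC-seq and 2052 HIF2α windows were called in tumours, 268 H3K27ac and 1205 HIF2α windows in metastases, and 2868 ATAC-seq windows in cell lines. Windows of 100 kb, which are fewer, gave 3817 H3K27ac and 3315 HIF2α calls in tumours, 9 HIF2α calls in metastases, and 3079, 6075 and 6251 calls in cell lines. A pseudocount of 0.1 kb gave 28 H3K27ac windows in metastases, and 2 kb gave 6 HIF2α windows. Without libraries of low covered length, 396 ATAC-seq windows in tumours were called, and 51 HIF2α windows and 3 HIF2α regions in metastases. All metastasis libraries gave 135 H3K27ac and 56 HIF2α windows. Leaving out each cell line in turn gave 3170 to 5361 ATAC-seq windows, the lowest without 769P, 6946 to 8224 H3K27ac windows and 8396 to 9743 HIF2α windows. With total covered length as covariate, also chosen after seeing the data, the share of lost windows closer to tumours was 100% in ATAC-seq, 98.36% in H3K27ac and 96.73% in HIF2α metastases, and 85.8%, 77.73% and 70.81% in cell lines (in ATAC-seq over the 176 of 187 called windows whose mean length also fell). For gained windows it was 83.51% in H3K27ac and 81.83% in HIF2α metastases, and 51.32% and 42.29% in cell lines. The gene locus, gene list and motif alternatives were not run.

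Other splits of the same libraries into groups of the same sizes were drawn, 100 for each comparison with the real split included. In tumours against normal kidney the real split called most H3K27ac windows (5959, highest other 725, next 24) and regions (1510, highest other 0). The same held for HIF2α windows (5322, highest other 445) and regions (124, highest other 0), which argues against chance. In ATAC-seq windows 2 splits, the real one included, called as many as the real one (255, highest other 984, next 12). In metastases against tumours the real split called most HIF2α windows (18, highest other 6). For H3K27ac windows 4 splits, the real one included, called 53 or more (highest other 898), and for HIF2α regions 2 called 9 or more (highest other 561). These ranks were not adjusted over the comparisons, so that chance is not excluded where another split called as many as the real one. Splits that call several times the real number, as in ATAC-seq windows of tumours against normal kidney and in H3K27ac windows and HIF2α regions of metastases, point to a structure of the samples beyond their groups. These splits ignore the donor pairs. Among 100 that part all 11 pairs, added after seeing the data, the real one called most in windows of H3K27ac (highest other 1544) and HIF2α (1262) and in their regions (0 and 0), and in ATAC-seq windows 2 splits called as many (highest other 934), and in ATAC-seq regions, with 0 called, all did (highest other 951). In cell lines the real split called most in windows of ATAC-seq (5178, highest other 2447), H3K27ac (9431, highest other 5272) and HIF2α (10821, highest other 4560). Where 0 were called, all 100 splits gave as many: ATAC-seq windows in metastases (highest other 1052), ATAC-seq regions in each comparison (highest other 0, 1 and 0), H3K27ac regions in metastases and cell lines (highest other 0) and HIF2α regions in cell lines (highest other 0).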

Other observations

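The tests of bands and arms in this part were chosen after the window results had been seen. Some chromosome bands held more windows with gained H3K27ac in primary tumours than expected from the share of all windows. At 21q22.12, a band known to hold the transcription factor gene RUNX1, 14 of 40 windows gained H3K27ac, and at 14q13.1, a band known to hold the oxygen-sensing prolyl hydroxylase gene EGLN3, 11 of 28 did, against 7.51% of all windows (Fisher's exact test over 717 bands, adjusted p = 0.000453 and 0.000701). At 14q13.1 HIF2α coverage also rose at 8 of 31 windows, against 4.37% of all (adjusted p = 0.0150). Gains of both were over-represented at 2q37.1 as well, with 20 of 90 windows in H3K27ac and 14 of 89 in HIF2α (adjusted p = 0.00134 and 0.0150). At 6p21.1, a band known to hold VEGFA, HIF2α rose at 14 of 109 windows (adjusted p = 0.0304). In all, 19 bands were over-represented among H3K27ac gains and 7 among HIF2α gains. Neighbouring windows are not independent, so these p-values are too small, and no window was assigned to a gene.

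Losses were over-represented in 39 bands for H3K27ac and in 7 of 736 for HIF2α. H3K27ac fell at 24 of 56 windows of 3p14.3, at 32 of 119 windows of 3p21.31 and at 13 of 23 windows of 4p13, against 9.62% of all windows (adjusted p = 5.32e-08, 1.36e-05 and 9.60e-06). HIF2α fell at 11 of 21 windows of 13q32.2 and at 20 of 74 windows of 10q25.1, against 8.96% of all (adjusted p = 0.000325 and 0.00162). By arm, 220 of 999 windows of 3p lost H3K27ac and 182 of 1250 lost HIF2α (adjusted p = 9.78e-31 and 2.45e-09), and 18.4% of those of 4p lost H3K27ac (adjusted p = 1.28e-08). On 10p, 13.6% of windows gained H3K27ac and 7.5% gained HIF2α (adjusted p = 2.83e-05 and 0.0144).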
